A study of Homo sapiens with 12 samples.

How the data were processed

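Total RNA from MCF7 cells with a doxycycline-inducible hairpin against CTR9 was extracted with a Qiagen RNeasy Plus kit, labelled with biotin and hybridised to the Affymetrix Human Transcriptome Array, with 1 array per sample, per the labels' protocols and the submitters' design text. The 12 arrays formed 4 groups of 3, without or with 500 ng/ml doxycycline (Dox) and with DMSO or 10 nM oestradiol (E2) for 4 h. The deposited values are log2 expression per transcript cluster, summarised by the authors. The submitters' processing notes name the Affymetrix Expression Console and the Transcriptome Analysis Console, and the versions of both programs, the summarisation and the normalisation are not given in the sources used here. The log2 scale was read from the values, which ran from 1.90 to 14.8, and the array medians of 6.27 to 6.44 differed, so the summarised values had not been forced to a single distribution. The genome build is not given either, and no coordinates are reported.

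The value table held 70523 features. Of these, 2995 control features were left out of the comparisons, and 67528 transcript clusters were tested. Of these 23781 carried 1 gene symbol, 1543 carried several and 42204 carried none. The single-symbol clusters covered 22465 genes, 479 of them with more than 1 cluster, in which case the cluster with the highest mean represented the gene. An Entrez identifier in the RefSeq table matched 21497 of these clusters, and 0 symbols had to be updated. The 12 values of 1673 clusters repeated those of another cluster, and these were kept.

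A model with 4 group means was fitted to the deposited log2 values of all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), with 8 residual and 4.02 prior degrees of freedom. The contrasts were E2 against DMSO without and with Dox, Dox against no Dox in DMSO and in E2, their interaction, and the average E2 and Dox effects. The pair of E2 comparisons shares no arrays, nor does the pair of Dox comparisons, while all contrasts share the estimate of spread. P-values were two-sided and adjusted by the Benjamini-Hochberg method over all clusters, with a threshold of 0.05. Fold change is given as a log2 difference of group means. The depth behind a value is not defined for arrays, and the 3 arrays per group limit the precision. A cluster's response to E2 counted as smaller with Dox where the interaction had the opposite sign to the average E2 effect, over the clusters that passed for that average, which is orthogonal to the interaction in this balanced design.

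Genes were named by a fixed rule. For each of the 4 simple contrasts these were the 10 largest rises and the 10 largest falls among single-symbol clusters that passed the threshold and had all 3 arrays of one group above all 3 of the other. For the interaction up to 10 per direction were taken by size, and the 5 smallest p-values where none passed. CTR9, the other PAF1 complex members, ESR1, PGR, GREB1 and TFF1 were always named, and up to 4 members with the smallest p came from each gene list. There were 22 gene lists with 448 memberships of 443 distinct genes, and 373 memberships were measured. MYC, SLC7A5, STC2, TFF3 and XBP1 each belong to the oestrogen-induced list and to another list. The list of mitochondrially encoded genes had 0 of 15 members measured and gave no result. Lists were tested with limma's camera with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists within a contrast, and members were also counted adjusted over the list alone. The groups, contrasts, tests, gene lists, naming rule and most alternatives were chosen before the data were examined.

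The fit was tested on simulated data with 67528 clusters. With 100 clusters changed by 1 log2 unit it called 100% for E2 without Dox, 93% for E2 with Dox, 99% for Dox in DMSO, 98% for Dox in E2 and 91% for the interaction. For changes of 0.5 it called 71%, 60%, 74%, 74% and 27%. In the same order, 9 of 180, 8 of 161, 7 of 180, 4 of 176 and 12 of 130 calls were false. The simulated noise was independent between clusters and arrays, with the same SD on every array, and 200 clusters were changed. The real arrays differed in spread, their residuals were correlated and many more clusters were called. These rates therefore check the fitting steps and do not give the rates of the real fit.

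Alternatives were a replicate block, no intensity trend, a filter on low signal, quantile normalisation, median centring, array weights, clusters of 1 gene only, a fit of only the groups compared, an unmoderated test with a 2-fold change, the mean over a gene's clusters for the lists, and leaving out each array in turn. Cyclic loess, repeated clusters counted once, and the gene lists without replicate 2 of the Dox and DMSO group were chosen after seeing the data. Without 1 array the group keeps 2 arrays and the spread is pooled over the groups. The groups are then unequal and E2-responsive clusters are chosen anew, so in those fits the average E2 effect is not orthogonal to the interaction. No array carries doxycycline without the hairpin, so an effect of doxycycline itself cannot be told apart from that of the hairpin, and "with Dox" names both.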

Results

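Gene expression was measured on 12 Affymetrix human transcriptome arrays hybridised with RNA from MCF7, an established breast cancer cell line that depends on oestrogen receptor alpha. The cells carried a short hairpin RNA (shRNA) that is switched on by doxycycline (Dox) and is directed against CTR9, a subunit of the PAF1 complex, which accompanies RNA polymerase II during transcript elongation. Cells grew without Dox or with 500 ng/ml Dox for 4 days in full medium and for another 3 days in stripped medium, and then received the solvent DMSO or 10 nM oestradiol (E2) for 4 h. The design therefore held 4 groups of 3 arrays, and the small number of arrays limits the precision of every value. The median deposited log2 value of an array lay between 6.27 and 6.44. Replicate 2 of the Dox and DMSO group deviated most from its group mean (root mean square 0.163 log2 units), followed by replicate 3 of that group (0.143) and replicate 3 of the Dox and E2 group (0.134). The other 9 arrays lay between 0.0752 and 0.105. The submitters' design text describes 3 independent experiments, and p-values measure the spread between the arrays of those experiments. All p-values are two-sided limma values adjusted by the Benjamini-Hochberg method unless stated otherwise, and an exact test on 1 gene with 3 arrays against 3 could not give a p below 0.1. The stated aim of the experiment was to find genes regulated by CTR9 across the genome, and its title concerns the part CTR9 plays in oestrogen signalling.

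CTR9 itself was lower in both groups with Dox. Its mean log2 level in DMSO was 8.66 ± 0.05 (SD, n = 3) without Dox and 7.09 ± 0.17 with Dox, a 2.98-fold decrease (log2 change −1.58, SE 0.0747, adjusted p = 2.92e-07). In E2 the level was 9.05 ± 0.05 without Dox and 7.29 ± 0.01 with Dox, a 3.40-fold decrease (log2 change −1.77, adjusted p = 1.08e-07). Among the other subunits of the complex, PAF1 fell with Dox in DMSO (−0.31, adjusted p = 0.00887) and had a log2 change of −0.15 in E2 (adjusted p = 0.237). SKIC8 (WDR61), a subunit shared with the SKI complex of cytoplasmic RNA decay, rose in DMSO (0.36, adjusted p = 0.00500) and in E2 (0.32, adjusted p = 0.0108). The SKIC8 call in E2 ended without replicate 1 of the group with E2 and no Dox (adjusted p = 0.0599), without its replicate 2 (0.0587) and after median centring of the arrays (0.0627). LEO1 had a log2 change of −0.21 in DMSO (adjusted p = 0.0818), and the log2 change of CDC73 and of RTF1 was 0.01. Of 6 measured subunits 1 rose and 2 fell in DMSO (1 and 3 adjusted over the list alone, adjusted p = 0.863 with an estimated correlation). ESR1, which encodes oestrogen receptor alpha, fell with Dox 1.38-fold in DMSO (log2 change −0.47, adjusted p = 0.000146) and 1.30-fold in E2 (−0.38, adjusted p = 0.000653).

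**Figure D1:**
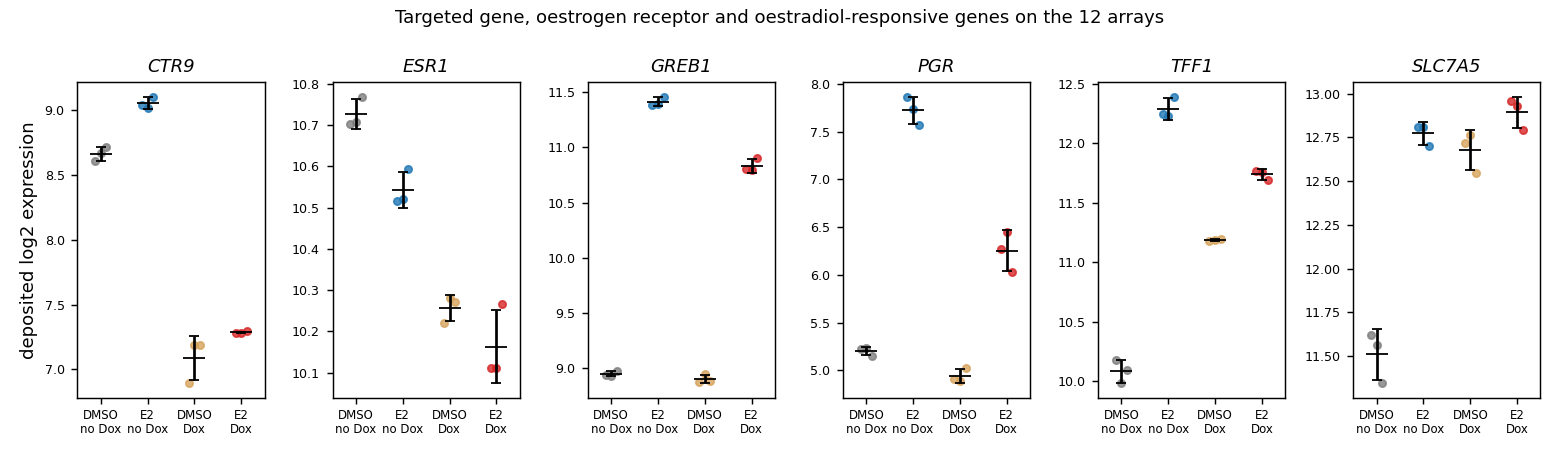
Deposited log2 expression (vertical axes, a separate scale per gene) of CTR9, ESR1, GREB1, PGR, TFF1 and SLC7A5 on each of the 12 arrays (points) in the 4 groups, with the group mean and SD (bars). CTR9 and ESR1 lay lower on all arrays with Dox than on all without it in the same hormone treatment, and TFF1 lay at 10.08 ± 0.10 without Dox and 11.19 ± 0.01 with Dox in DMSO.

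Oestradiol without Dox, the comparison that shows the hormone response of these cells, raised well known targets of the oestrogen receptor within 4 h. RASGRP1, an activator of Ras GTPases, rose 6.75-fold (log2 change 2.76, SE 0.0875, n = 3 against 3, adjusted p = 5.97e-09) and the progesterone receptor gene PGR 5.73-fold (SE 0.104). GREB1, an oestrogen receptor cofactor, rose 5.53-fold (SE 0.0483) and the secreted trefoil peptide gene TFF1 4.61-fold (SE 0.0597). NPY1R, a neuropeptide Y receptor, rose by 2.10 on the log2 scale, the fatty acid elongase ELOVL2 by 1.93 and the MYB-family factor MYBL1 by 1.91. MYBL1 has 2 clusters, and its other cluster did not pass for E2 without Dox or with Dox. The transcription factor MYC rose by 1.83, the trafficking GTPase RAB31 by 1.82 and the matrix protein gene THBS1 by 1.74. The largest decreases were smaller. TP53INP1, a stress protein induced by p53, fell 2.36-fold (log2 change −1.24, SE 0.0719, adjusted p = 8.30e-07) and the phospholipase gene LIPH 2.14-fold. The xenobiotic-metabolising cytochrome CYP1A2 changed by −1.04, the netrin receptor UNC5C and the neuronal membrane protein SLITRK6 by −1.03 each and the cytokine receptor IL1R1 by −1.02. The growth factor TGFB3 changed by −0.96, CREBRF by −0.95, the polysialyltransferase ST8SIA4 by −0.91 and the stem cell factor SALL4 by −0.89.

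In all, 2271 of 67528 transcript clusters rose and 1304 fell with E2 in the absence of Dox, and 673 and 155 of them changed at least 1.5-fold. Of the clusters that name a single gene, those that rose covered 1347 genes and those that fell 724 genes. At an unadjusted p under 0.05, 9116 clusters differed. The total of 3575 dropped to 2351 without replicate 2 of the DMSO group without Dox, to 2314 without replicate 1 of the E2 group without Dox and to 2232 without its replicate 2. Higher clusters made up 63.5% of the calls, and after median centring of each array 2155 rose and 588 fell (78.6%).

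Of 41 measured oestrogen-induced genes, 35 rose and 0 fell (38 rose adjusted over the list alone), among them CXCL12, a chemokine, by 1.48 (median change 0.81, adjusted p = 0.000225 with an estimated correlation). Of 18 oestrogen-repressed genes, 12 fell (14 adjusted over the list alone) and 2 rose (median −0.37, adjusted p = 0.0109 with an estimated correlation). Examples were BMF, a pro-apoptotic BCL family gene, at −0.80, the cyclin CCNG2 at −0.69 and the ephrin EFNA1 at −0.62. All 21 ribosome biogenesis genes rose (21 adjusted over the list alone), including NOP16 by 1.11, RRP12 by 0.76, NOP2 by 0.73 and POLR1A, the largest subunit of RNA polymerase I, by 0.62 (median 0.73, adjusted p = 0.00303 with an estimated correlation). Of 26 genes of DNA replication and the G1/S transition, 18 rose and 0 fell (23 rose adjusted over the list alone, median 0.44, adjusted p = 0.00758 with an estimated correlation). They included DTL at 1.20, the helicase subunits MCM7 at 0.64 and MCM3 at 0.60, and MCM10 at 0.73.

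Further lists passed only with the preset correlation. In the list of ATF4 targets and the amino acid response, 7 of 25 genes rose and 3 fell (13 and 3 adjusted over the list alone, adjusted p = 0.0589 with an estimated correlation). STC2 was at 1.53, the amino acid transporter subunits SLC7A5 at 1.26 and SLC3A2 at 0.54, and the folate enzyme MTHFD2 at 0.54. STC2 and SLC7A5 also belong to the oestrogen-induced list, as do MYC and XBP1 below. Of 14 oestrogen receptor cofactors 1 rose, TFAP2C by 0.37, and 5 fell (1 and 7 adjusted over the list alone), including the membrane oestrogen receptor GPER1 at −0.59 and the coactivator NCOA2 at −0.48 (adjusted p = 0.394 with an estimated correlation). Without replicate 2 of the Dox and DMSO group, which enters here through the spread alone, the cofactor list did not pass with the preset correlation (adjusted p = 0.0866). Among 18 immediate early genes 4 rose, led by MYC and KLF10 (0.50), and 2 fell, CCN2 (−0.53) and DUSP1 (−0.25), with the same counts adjusted over the list alone (adjusted p = 0.613 with an estimated correlation). Among 24 genes of G2/M and mitosis MAD2L1 rose by 0.25 and KIF20A (−0.31) and BUB1 (−0.37) fell, while 8 fell adjusted over the list alone (adjusted p = 0.569 with an estimated correlation). HSPD1 (0.37), HSP90AB1 (0.22) and DNAJA1 (0.38) rose among 12 heat shock genes, 5 adjusted over the list alone (adjusted p = 0.394 with an estimated correlation). XBP1 (0.43) and HYOU1 (0.25) rose and SEL1L (−0.30) fell among 16 genes of the unfolded protein response, with 6 higher and 2 lower adjusted over the list alone (adjusted p = 0.372 with an estimated correlation).

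No list-wide shift passed in the remaining measured lists. In the hypoxia and glycolysis list 4 of 19 genes rose, including the glucose transporter SLC2A1 by 1.01, and 2 fell, including NDRG1 at −0.33 (5 and 4 adjusted over the list alone, adjusted p = 0.616 with an estimated correlation). Of 19 p53 targets 3 rose, including AEN by 0.76 and GDF15 by 0.30, and 3 fell, including SESN1 at −0.47 and DDB2 at −0.31 (3 and 4 adjusted over the list alone, adjusted p = 0.963 with an estimated correlation). Of 13 luminal markers 5 rose, including KRT19 (0.32), KRT18 (0.26) and TFF3 (0.39), and 2 fell, including SPDEF (−0.41), with the same counts adjusted over the list alone (adjusted p = 0.616 with an estimated correlation). DHCR7 (0.29) and SQLE (0.22) rose among 16 cholesterol synthesis genes (2 higher and 1 lower adjusted over the list alone, adjusted p = 0.519 with an estimated correlation). CYC1 (0.23) and COX6C (0.29) rose among 20 nuclear-encoded genes of oxidative phosphorylation (2 adjusted over the list alone, adjusted p = 0.731 with an estimated correlation). HERC5 (0.32) rose among 27 interferon-stimulated genes (1 adjusted over the list alone, adjusted p = 0.963 with an estimated correlation). CTR9, at 0.39 (adjusted p = 0.00763), was the 1 gene of 6 in the PAF1 complex that rose (1 higher and 2 lower adjusted over the list alone, adjusted p = 0.963 with an estimated correlation). In limma 0 of 8 histone genes, 6 basal, 14 mesenchymal and 10 leukocyte and endothelial markers passed, over all clusters or adjusted over the list alone. At an unadjusted p under 0.05 there was 1 such histone gene, H2BC14 at −0.14, and 0 of the markers.

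**Figure D2:**
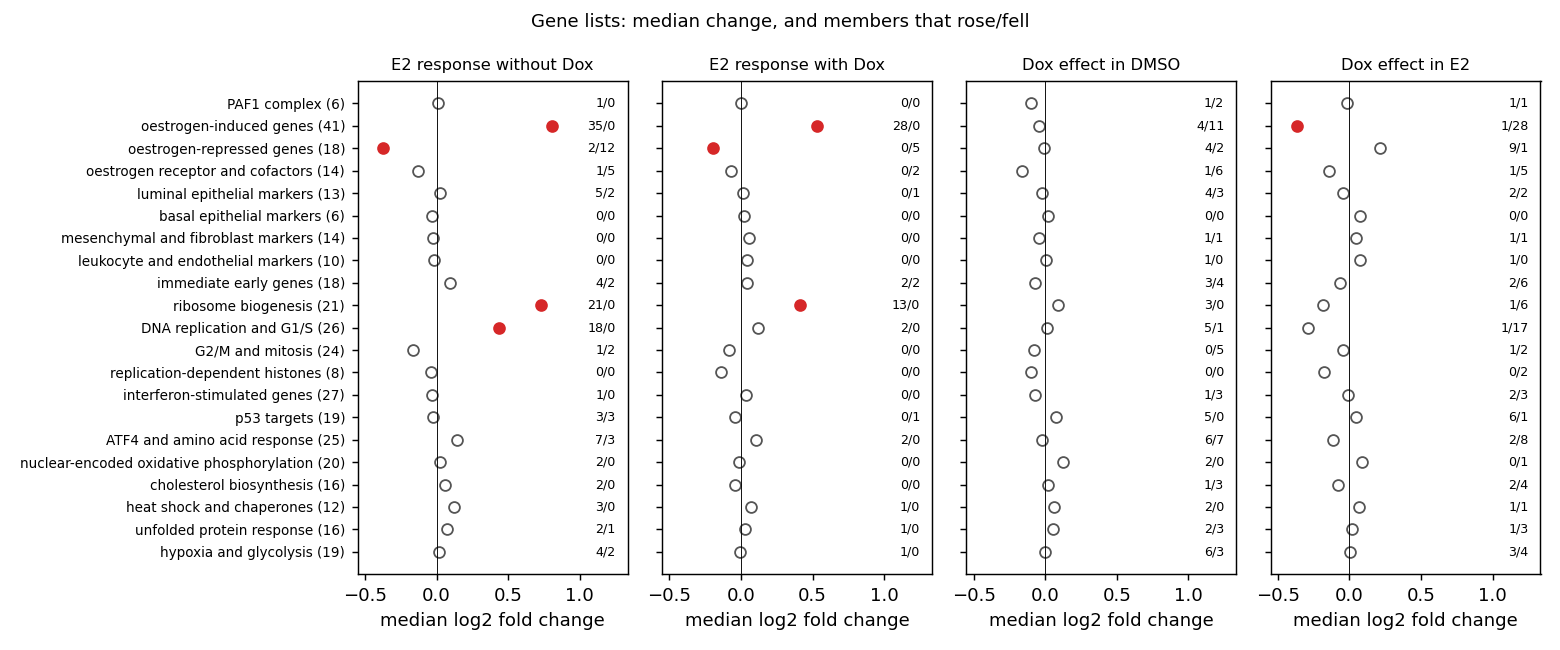
Median log2 fold change (horizontal axis) of the measured members of each gene list (rows, number measured in brackets) in the 4 comparisons (panels), with the numbers of members that rose and fell at the right. Filled red points mark lists with an adjusted p under 0.05 in limma's camera test with an estimated correlation, among which the median of the oestrogen-induced genes was 0.81 for E2 without Dox and −0.36 for Dox in E2.

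With Dox present, E2 raised many of the same genes by smaller amounts. GREB1 rose 3.82-fold (log2 change 1.93, SE 0.0483, adjusted p = 2.45e-09), RASGRP1 3.65-fold (SE 0.0875), IGFBP4, a binding protein of insulin-like growth factors, 3.08-fold (SE 0.0684) and PGR 2.48-fold (SE 0.104). MYC rose by 1.28, ELOVL2 and the amino acid transporter SLC6A14 by 1.27 each, NPY1R by 1.26, the mitochondrial phosphatase PPM1K by 1.24 and MYBL1 by 1.19, while TFF1 rose by 0.55 (adjusted p = 0.000708). SLITRK6 (−0.94), ST8SIA4 (−0.92), CREBRF (−0.65), the pseudogene CPHL1P (−0.65), SALL4 (−0.64), the lactate receptor HCAR1 (−0.63), TCP11L2 (−0.63), the dopamine receptor DRD1 (−0.62), PRICKLE2-AS3 (−0.62) and ANKRD30B (−0.62) fell. Several of these calls were close to the threshold. In a fit of the 6 arrays with Dox alone the adjusted p was 0.147 for SLC6A14, 0.0938 for SLITRK6, 0.0785 for CREBRF, 0.282 for CPHL1P, 0.0583 for SALL4, 0.140 for TCP11L2, 0.120 for PRICKLE2-AS3 and 0.232 for ANKRD30B. Without replicate 1 of the Dox and E2 group the adjusted p was 0.165 for CPHL1P, 0.201 for ANKRD30B, 0.0916 for SLC6A14 and 0.0565 for TCP11L2, and without its replicate 2 it was 0.184 for ANKRD30B, 0.0868 for SLC6A14 and 0.0525 for TCP11L2. Median centring ended the calls of SLC6A14 (adjusted p = 0.0594), CPHL1P (0.0870), TCP11L2 (0.0778) and ANKRD30B (0.0836). Quantile normalisation and cyclic loess ended those of CPHL1P (0.0544 and 0.0523) and ANKRD30B (0.0563 and 0.0663). The TCP11L2 call also ended without replicate 1 of the Dox and DMSO group (0.0515). The CPHL1P call ended without replicate 2 or 3 of that group, replicate 1 or 2 of the DMSO group without Dox or any 1 array of the E2 group without Dox (at most 0.0705). The ANKRD30B call further ended without any 1 array other than replicate 1 of the DMSO group without Dox and replicate 3 of the Dox and E2 group (at most 0.0968 for the arrays outside the Dox and E2 group). The arrays without Dox enter this comparison through the estimate of spread alone, and leaving one out does not move the log2 changes.

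With Dox 491 clusters rose and 248 fell with E2 (739 in all, against 8153 at an unadjusted p under 0.05), of which 101 and 33 changed at least 1.5-fold, and the single-gene clusters among them covered 337 and 119 genes. The count was 249 without replicate 1 of the Dox and E2 group, 276 without its replicate 2, and 396 without replicate 1 of the Dox and DMSO group. It was 482 without replicate 2 of the DMSO group without Dox, and 468 and 475 without replicates 1 and 2 of the E2 group without Dox, arrays that enter through the spread alone. Without replicate 3 of the Dox and E2 group it was 2176, and the split turned from 66.4% higher to 34.1% (743 higher and 1433 lower). A replicate block gave 2185 clusters and also turned the split, to 47.3% higher (1033 higher and 1152 lower). Median centring gave 364 clusters and a fit of the 6 arrays with Dox gave 87. Of the clusters raised by E2 without Dox, 471 also rose with Dox, where independent lists would share 16.5, and 184 fell in both, where independent lists would share 4.79, although no arrays were shared between these comparisons. Across all clusters the log2 changes had r = 0.516, a correlation across clusters that are not independent replicates.

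Among the lists, 28 of 41 oestrogen-induced genes rose with E2 in the presence of Dox (32 adjusted over the list alone, median 0.53, adjusted p = 0.000362 with an estimated correlation), with CXCL12 at 0.91. Of 18 oestrogen-repressed genes 5 fell, among them BMF (−0.46), TP53INP1 (−0.59), EFNA1 (−0.46) and PSCA (−0.42), and 0 rose (11 lower and 1 higher adjusted over the list alone, adjusted p = 0.0114 with an estimated correlation). Of 21 ribosome biogenesis genes 13 rose (21 adjusted over the list alone, median 0.41, adjusted p = 0.00596 with an estimated correlation), including NOP2 by 0.41 and NOLC1 by 0.60. Of 26 replication genes CCNE1 (0.36) and MCM3 (0.22) rose (11 adjusted over the list alone, median 0.12, adjusted p = 0.193 with an estimated correlation). The shifts of the lists of receptor cofactors, G2/M and mitosis, histones, ATF4 and heat shock passed with the preset correlation only, with adjusted p = 0.218, 0.550, 0.193, 0.193 and 0.550 with an estimated correlation. Without replicate 2 of the Dox and DMSO group the cofactor, mitotic and histone lists did not pass with the preset correlation either (adjusted p = 0.170, 0.408 and 0.0610). In the luminal list the median (0.02) and mean (−0.03) had opposite signs and the test pointed down, and in the hypoxia list the median (−0.01) and mean (0.01) differed in sign and the test pointed down, neither past the threshold.

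Dox in DMSO, the comparison that shows the effect of the hairpin and of doxycycline without hormone, raised VTCN1 and CEACAM5 most among the named genes. VTCN1, an inhibitory ligand of T cells, rose 14.4-fold (log2 change 3.84, SE 0.0573, n = 3 against 3, adjusted p = 5.17e-12) and CEACAM5, carcinoembryonic antigen, 9.82-fold (SE 0.0988). CLCA2, an epithelial regulator of chloride currents, rose 6.08-fold (SE 0.200) and the relaxin-family peptide gene INSL4 4.92-fold (SE 0.156). The pseudogene CYP4Z2P rose by 2.02, IFI6, an interferon-stimulated gene, by 2.00, CEACAM6 by 1.99, the fatty acid hydroxylase CYP4Z1 by 1.79, the epithelial transcription factor GRHL1 by 1.77 and EPAS1, a hypoxia-inducible factor subunit, by 1.74. CEACAM5 and CEACAM6, as well as CYP4Z1 and CYP4Z2P, are near copies whose RNA can hybridise to the probes of the other, so their separate values are uncertain. BMP7, a bone morphogenetic protein, fell 3.28-fold (log2 change −1.71, SE 0.0441, adjusted p = 1.19e-09) and SPMAP2 3.00-fold, followed by CTR9. The endocytic adaptor HIP1 and the glypican GPC4 changed by −1.33 each, the matrix protein HMCN1 by −1.32, the steroid dehydrogenase HSD17B14 and the glucosyltransferase POGLUT3 by −1.31 each, the membrane skeleton gene EPB41L2 by −1.29 and the glycosyltransferase GALNT12 by −1.26. TFF1 rose 2.15-fold (adjusted p = 6.23e-07), while PGR (−0.26, adjusted p = 0.163) and GREB1 (−0.05, adjusted p = 0.698) did not pass.

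Dox in DMSO raised 3288 clusters and lowered 2797 (6085 in all, against 13993 at an unadjusted p under 0.05), of which 841 and 350 changed at least 1.5-fold. The single-gene clusters among them covered 1293 genes that rose and 1748 that fell. The direction of the whole set depended on the scaling of the arrays and on the clusters included. Higher clusters made up 54.0% of the calls in the deposited values, 39.9% after median centring (2103 higher and 3173 lower), 45.2% after quantile normalisation, 42.5% among clusters of 1 gene, 49.9% after cyclic loess and 49.8% under the filter on low signal. The share was 49.5% without replicate 2 of the Dox and DMSO group (3190 higher and 3260 lower). Without replicate 1 or replicate 2 of the DMSO group without Dox the count was 3793 or 3746, and a fit of the 6 arrays in DMSO gave 3630.

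For Dox in DMSO none of the 21 measured lists passed with an estimated correlation. Of 14 oestrogen receptor cofactors 6 fell, including ESR1, the coactivator NCOA1 (−0.63) and the luminal factor GATA3 (−0.27). TFAP2C rose by 0.47 (9 lower and 1 higher adjusted over the list alone, adjusted p = 0.574 with an estimated correlation). Of 41 oestrogen-induced genes 11 fell, including IGFBP4 (−0.85) and CA12 (−0.75), and 4 rose, including TFF1 and SLC7A5 (1.17), with 14 lower and 10 higher adjusted over the list alone (adjusted p = 0.863 with an estimated correlation). Of 18 oestrogen-repressed genes INHBB (1.23), TGFB2 (1.01), PSCA (0.70) and BCAS1 (0.69) rose and 2 fell (4 and 4 adjusted over the list alone, adjusted p = 0.863 with an estimated correlation). Of 19 p53 targets 5 rose, including GDF15 (0.93), AEN (0.67), RPS27L (0.39) and ZMAT3 (0.26), and 0 fell (5 adjusted over the list alone, adjusted p = 0.574 with an estimated correlation). NPM1 (0.36), NOP16 (0.33) and NIP7 (0.23) rose among 21 ribosome biogenesis genes (3 adjusted over the list alone, adjusted p = 0.759 with an estimated correlation). ATP5PO (0.18) and COX6C (0.29) rose among 20 oxidative phosphorylation genes (5 adjusted over the list alone, adjusted p = 0.663 with an estimated correlation). Without replicate 2 of the Dox and DMSO group, the array that deviated most, the shifts of the p53, ribosome biogenesis and oxidative phosphorylation lists did not pass with the preset correlation either (adjusted p = 0.0816, 0.273 and 0.197).

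In the hypoxia list NDRG1 (0.85), PDK1 (0.79) and SLC2A1 (0.35) were among 6 of 19 genes that rose, and EGLN3 (−0.75) was among 3 that fell (7 and 3 adjusted over the list alone, adjusted p = 0.681 with an estimated correlation). In the ATF4 list 6 of 25 genes rose, including SLC7A5 and SLC3A2 (0.53), and 7 fell, including ATF4 (−0.38) and the cystine transporter SLC7A11 (−0.68), with 6 and 10 adjusted over the list alone (adjusted p = 0.863 with an estimated correlation). ELF3 (0.65) and KRT18 (0.39) were among 4 of 13 luminal markers that rose, and MUC1 (−0.65) and SPDEF (−0.32) among 3 that fell (6 and 3 adjusted over the list alone). Of 18 immediate early genes 4 fell, including EGR1 (−0.71), DUSP6 (−0.58) and FOS (−0.40), and 3 rose, including KLF4 (0.31), with 5 and 6 adjusted over the list alone. FOXM1 (−0.46), AURKA (−0.30), UBE2C (−0.20) and TPX2 (−0.35) were among 5 of 24 mitotic genes that fell (7 lower and 2 higher adjusted over the list alone). The median of the mitotic list was −0.08 (adjusted p = 0.170 with the preset correlation and 0.863 with an estimated correlation). Without replicate 2 of the Dox and DMSO group the median was −0.18 (adjusted p = 0.00218 with the preset correlation, the only one run without that array). MCM4 (0.29), RRM2 (0.47), CCNE2 (0.75) and MCM10 (0.25) were among 5 of 26 replication genes that rose, while 1 fell (7 and 1 adjusted over the list alone). IFI6 was the 1 interferon-stimulated gene of 27 that rose, while OAS3 (−0.35), IFI35 (−0.41) and PARP9 (−0.27) fell (2 and 4 adjusted over the list alone). IDI1 (0.38) rose and SREBF2 (−0.32), STARD4 (−0.29) and FDPS (−0.22) fell among 16 cholesterol genes, with the same counts adjusted over the list alone. DNAJB1 (0.31) and HSP90AA1 (0.26) rose among 12 heat shock genes (3 higher and 1 lower adjusted over the list alone). HERPUD1 (0.79) was among 2 genes of the unfolded protein response that rose while EDEM1 (−0.41) was among 3 that fell, with the same counts adjusted over the list alone. Fibronectin, FN1 (−1.11), fell and SNAI2 (0.28) rose among 14 mesenchymal markers, and CD68 (0.50), a lysosomal protein also used as a macrophage marker, was the 1 of 10 leukocyte and endothelial markers that rose. Both counts were the same adjusted over the list alone. In limma 0 of 6 basal markers and 8 histone genes passed, over all clusters or adjusted over the list alone, against 0 and 2 at an unadjusted p under 0.05. The medians of the oestrogen-repressed (−0.01), luminal (−0.02) and hypoxia (−0.00) lists had the opposite sign to their means (0.15, 0.03 and 0.08) and tests, and the basal list had a median of 0.02, a mean of −0.01 and a test pointing up.

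Dox in E2, which compares hormone-treated cells with and without doxycycline and the hairpin it induces, changed the same leading genes and also lowered oestrogen-induced genes. VTCN1 rose 14.8-fold (log2 change 3.89, SE 0.0573, adjusted p = 4.47e-12), CEACAM5 10.6-fold (SE 0.0988) and CLCA2 5.75-fold (SE 0.200), and CYP4Z2P (2.18), CEACAM6 (2.13), INSL4 (2.02), EPAS1 (1.97), IFI6 (1.91), CYP4Z1 (1.81) and the trichohyalin-like gene TCHHL1 (1.54) also rose. After CTR9, BMP7 fell 3.11-fold (log2 change −1.64, SE 0.0441), the skin ceramide enzyme CYP4F22 2.88-fold, ELOVL2 2.81-fold, PGR 2.77-fold (SE 0.104, adjusted p = 4.58e-06) and RASGRP1 2.56-fold. RAB31 (−1.35), HIP1 (−1.33), the pseudogene RCN1P2 (−1.25) and the interleukin receptor gene IL17RB (−1.24) were the others among the 10 largest decreases. GREB1 fell by 0.58 (adjusted p = 1.48e-05) and TFF1, which Dox had raised in DMSO, changed by −0.55 (adjusted p = 0.000108).

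In E2, 2320 clusters rose with Dox and 3172 fell (5492 in all, against 13114 at an unadjusted p under 0.05), of which 523 and 441 changed at least 1.5-fold, covering 1105 and 1971 genes with single-gene clusters. Without replicate 1 or replicate 2 of the E2 group without Dox the count was 3396 or 3409. Higher clusters made up 42.2% of the calls, and 22.5% after median centring (1217 higher and 4191 lower). Between the 2 hormone treatments, which share no arrays, 1607 clusters rose with Dox in both, where independent lists would share 113, and 1974 fell in both, where independent lists would share 131. Another 24 clusters rose in DMSO and fell in E2, and 0 did the reverse. Across clusters, which are not independent replicates, the log2 changes had r = 0.679.

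Of 41 oestrogen-induced genes 28 fell with Dox in E2 and 1 rose (30 and 3 adjusted over the list alone, median −0.36, adjusted p = 0.0137 with an estimated correlation), including IGFBP4 (−0.95) and CXCL12 (−0.79). Of 18 oestrogen-repressed genes 9 rose, including BCAS1 (0.94), TP53INP1 (0.81), INHBB (0.80) and PSCA (0.80), and 1 fell (11 and 2 adjusted over the list alone, adjusted p = 0.123 with an estimated correlation). Of 26 replication genes 17 fell, including MCM7 (−0.55), MCM2 (−0.54), MCM3 (−0.44) and MCM5 (−0.33), and 1 rose (20 and 2 adjusted over the list alone, adjusted p = 0.123 with an estimated correlation). Of 21 ribosome biogenesis genes 6 fell, including RRP12 (−0.29), and 1 rose (11 and 1 adjusted over the list alone, adjusted p = 0.190 with an estimated correlation). In the ATF4 list 8 of 25 fell, including ATF4 (−0.50), SLC7A11 (−0.84) and the serine synthesis enzyme PSAT1 (−0.80), and 2 rose, including DDIT4 (0.56), with 11 and 6 adjusted over the list alone (adjusted p = 0.337 with an estimated correlation). EGR1 (−0.83), DUSP6 (−0.56), FOS (−0.48) and MYC (−0.38) were among 6 of 18 immediate early genes that fell, while ATF3 (0.34) and DUSP1 (0.22) rose (6 and 2 adjusted over the list alone, adjusted p = 0.691 with an estimated correlation). The linker histone genes H1-4 (−0.22) and H1-3 (−0.40), which belong to a family of similar copies, fell among 8 histone genes (5 adjusted over the list alone, adjusted p = 0.337 with an estimated correlation). GDF15 (0.64), ZMAT3 (0.46) and RPS27L (0.45) were among 6 of 19 p53 targets that rose and TNFRSF10B (−0.25) fell (7 and 1 adjusted over the list alone, adjusted p = 0.337 with an estimated correlation). After median centring the median of the p53 list was −0.04. The cofactor list (1 rose and 5 fell, 2 and 7 adjusted over the list alone) and the cholesterol list (2 rose and 4 fell, including SREBF2 at −0.33, 2 and 7 adjusted over the list alone) passed with the preset correlation and had adjusted p = 0.337 and 0.374 with an estimated correlation. Without replicate 2 of the Dox and DMSO group, which enters here through the spread alone, the immediate early, p53, ATF4 and cholesterol lists did not pass with the preset correlation (adjusted p = 0.0631, 0.0631, 0.0759 and 0.0589). Median, mean and test differed in sign in the mesenchymal (0.04, −0.01, up), interferon (−0.01, 0.04, down), unfolded protein (0.02, 0.01, down) and hypoxia (0.00, 0.03, down) lists, none past the threshold.

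The interaction compares the E2 response with Dox against that without Dox and bears on the part of CTR9 in oestrogen signalling. The rise of TFF1 was smaller with Dox (log2 difference of the responses −1.65, SE 0.0844, adjusted p = 1.19e-05), as were those of PGR (−1.21, SE 0.147, adjusted p = 0.00693) and GREB1 (−0.53, SE 0.0683, adjusted p = 0.00988). Other responses that were smaller with Dox were those of TIAM1 (−1.11), an activator of Rac, the amino acid transporter gene SLC7A5 (−1.05), which has a close pseudogene copy, CDCA7 (−0.89) and RASGRP1 (−0.89). The same held for NPY1R (−0.85), the replication-linked ubiquitin ligase adaptor DTL (−0.79), the transcription factor E2F6 (−0.78) and the proton pump subunit ATP6V1C2 (−0.76). Among genes that E2 lowered, the interaction was positive for CYP1A2 (0.70, adjusted p = 0.00310), UNC5C (0.66), TP53INP1 (0.65), CYP1A1 (0.52) and the nuclear receptor coregulator PNRC1 (0.45), where CYP1A1 and CYP1A2 are similar in sequence and uncertain as separate values. The mean CYP1A2 level was already lower with Dox in DMSO (8.02 against 8.95), and in E2 it was 7.68 with Dox and 7.91 without. For UNC5C and TP53INP1 the mean in DMSO was not lower with Dox (9.48 against 8.83 and 10.65 against 10.49). The calls of TP53INP1 and PNRC1 ended without any 1 array other than replicates 2 and 3 of the Dox and DMSO group and replicate 3 of the Dox and E2 group (adjusted p at most 0.118 and 0.102). The DTL call ended without any 1 array other than replicate 3 of the Dox and DMSO group (at most 0.184). The NPY1R call ended without any 1 of the 6 arrays without Dox or replicate 1 of the Dox and E2 group (at most 0.0819), and the GREB1 call without that last array (0.0536). The E2F6 call ended without replicate 1 or 2 of either E2 group or of the DMSO group without Dox, or replicate 3 of the E2 group without Dox (at most 0.0720). The CYP1A1 call ended without replicate 1 or 2 of either E2 group or replicate 2 of the DMSO group without Dox (at most 0.0638). The RASGRP1 call ended without replicate 1 or 3 of the DMSO group or replicate 1 or 2 of the E2 group, both without Dox (at most 0.0768). Median centring ended the calls of UNC5C (adjusted p = 0.127), SLC7A5 (0.0505) and CDCA7 (0.0505) as well as those of TP53INP1 (0.267), CYP1A1 (0.265), PNRC1 (0.318), RASGRP1 (0.0545), NPY1R (0.0991), DTL (0.216) and E2F6 (0.0693). Quantile normalisation and cyclic loess ended those of NPY1R (0.106 and 0.0597) and DTL (0.109 and 0.0708). Without the intensity trend the calls of DTL (0.0628), TP53INP1 (0.0520) and PNRC1 (0.0518) ended.

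**Figure D3:**
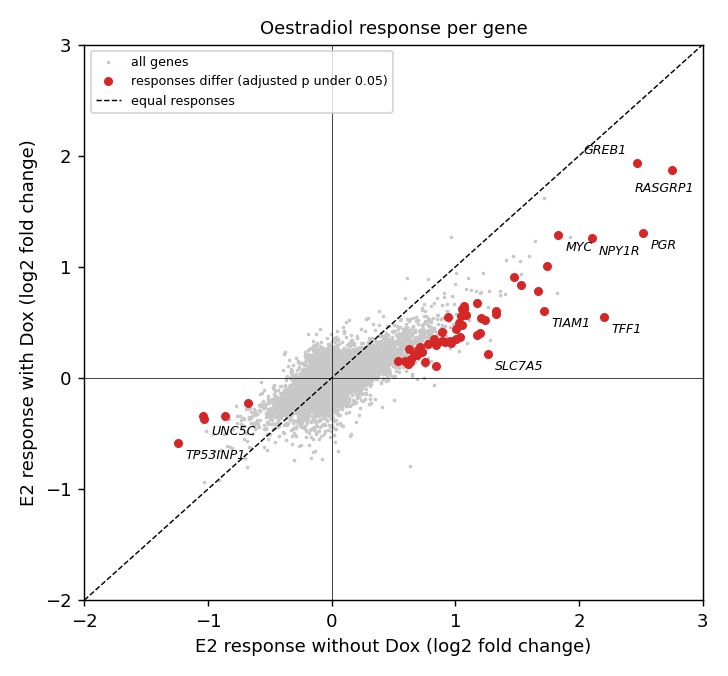
Log2 fold change with E2 without Dox (horizontal axis) and with Dox (vertical axis) for every gene with a single-gene cluster (grey), with genes whose 2 responses differ at an adjusted p under 0.05 in red and equal responses on the dashed line. All red points lie nearer to 0 on the vertical axis than on the horizontal axis, with TFF1 at 2.20 and 0.55.

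The interaction passed in 113 clusters (3743 at an unadjusted p under 0.05), 107 below 0 and 6 above 0, covering 51 and 5 genes. All 107 were clusters that rose with E2 without Dox and all 6 were clusters that fell, so each of the 113 had a smaller response with Dox. The count was 55, 41 and 51 without replicates 1, 2 and 3 of the DMSO group without Dox, and 46, 36 and 56 without those of the E2 group without Dox. It was 57 without replicate 1 of the Dox and DMSO group, and 36 and 48 without replicates 1 and 2 of the Dox and E2 group. The count was 63 without the intensity trend and 35 after median centring. Among lists, 9 of 41 oestrogen-induced genes had a smaller rise (25 smaller and 1 larger adjusted over the list alone, median −0.29, adjusted p = 0.00139 with an estimated correlation), including the receptor kinase gene RET (−0.58). MCM7 (−0.47), MCM10 (−0.50) and DTL passed among 26 replication genes (20 adjusted over the list alone, median −0.31, adjusted p = 0.00594 with an estimated correlation). In limma 0 of 21 ribosome biogenesis genes passed over all clusters, 14 passed adjusted over the list alone and 14 had an unadjusted p under 0.05 (median −0.30, adjusted p = 0.00860 with an estimated correlation), led by NOP2 (−0.32). The lists of oestrogen-repressed genes, ATF4 targets, cholesterol synthesis, luminal markers, immediate early genes and histones passed with the preset correlation only (adjusted p = 0.0780, 0.107, 0.107, 0.312, 0.480 and 0.321 with an estimated correlation). TP53INP1 passed in the first, SLC7A5 and SLC3A2 (−0.39) in the second and MYC (−0.55) among the immediate early genes. After quantile normalisation the median of the luminal list was 0.02. Without replicate 2 of the Dox and DMSO group the luminal and histone lists did not pass with the preset correlation (adjusted p = 0.311 and 0.332). The mitotic list had a median of 0.10 with all arrays (adjusted p = 0.175 with the preset correlation and 0.701 with an estimated correlation). Without that replicate its median was 0.15 (adjusted p = 4.72e-05 with the preset correlation, the only one run without that array). Median and mean differed in sign in the PAF1 complex (−0.00 and 0.02, test up) and hypoxia (0.01 and −0.06, test down) lists, where SLC2A1 (−0.57) passed.

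Averaged over both Dox states, E2 raised 2574 clusters and lowered 2331 (4905 in all), and averaged over both hormone treatments Dox raised 5807 and lowered 4871 (10678 in all). Higher clusters made up 52.5% of the calls for E2, and neither direction held throughout. Their share was 64.6% after median centring (2375 and 1301), 42.4% without replicate 3 of the Dox and E2 group (2840 and 3853) and 49.8% without replicate 3 of the Dox and DMSO group (2556 and 2574). For Dox they made up 54.4%, but 31.7% after median centring (3163 and 6819), 44.3% after quantile normalisation (4661 and 5868), 46.0% after cyclic loess (4813 and 5660), 49.9% under the filter on low signal (4967 and 4979) and 43.0% among clusters of 1 gene (2781 and 3685). Of the 2574 induced clusters 2384 (92.6%) had a smaller rise with Dox. The median log2 rise was 0.39 without Dox and 0.20 with Dox, with a ratio of mean responses of 0.515 (limma's camera test, unadjusted p = 5.45e-05 with an estimated correlation). Of the 2331 repressed clusters 1631 had a smaller fall, with medians of −0.29 and −0.23 and a ratio of 0.812 (unadjusted p = 0.180 with an estimated correlation). The repressed share changed when single arrays were left out. Without replicate 3 of the Dox and E2 group it was 38.1% of 3853 clusters. Without replicate 3 of the Dox and DMSO group it was 59.9% (limma's camera test, p = 0.857 at the preset correlation). Clusters were chosen anew in these unbalanced fits, where the choice is not orthogonal to the interaction and can itself move the share. Over both directions the share was 81.9%, and 57.7% without replicate 3 of the Dox and E2 group.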

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

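The test of single arrays for the smaller induction and the median centring of the clusters without a gene symbol were chosen only after the results were seen.

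The E2 response differed with Dox in 113 clusters by the test of the interaction, and each of these responses was smaller with Dox. The genes named for this difference were TFF1 (log2 interaction −1.65), PGR (−1.21), TIAM1 (−1.11), SLC7A5 (−1.05), CDCA7 (−0.89), RASGRP1 (−0.89), NPY1R (−0.85), DTL (−0.79), E2F6 (−0.78), ATP6V1C2 (−0.76) and GREB1 (−0.53) among induced genes. Among repressed genes they were CYP1A2 (0.70), UNC5C (0.66), TP53INP1 (0.65), CYP1A1 (0.52) and PNRC1 (0.45). Of these TFF1, PGR, TIAM1, ATP6V1C2 and CYP1A2 passed after each single array was left out and under each other alternative run for them, where the filter on low signal left PGR out and a fit of only the groups compared does not apply to the interaction. DTL reached an adjusted p of 0.184 and NPY1R of 0.0819 without replicate 2 of the E2 group without Dox, and the arrays and alternatives that ended each other call are named with the interaction results. By list, the difference had a median of −0.29 for the oestrogen-induced genes, −0.30 for ribosome biogenesis and −0.31 for DNA replication and G1/S. For some genes, such as SLC7A5 and CYP1A2, the level in DMSO already differed with Dox, as given with the interaction results.

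The pattern weighed here is the smaller rise of 92.6% of the 2574 E2-induced clusters with Dox. A single array was argued against as the whole cause, since the lowest share over the fits without 1 array was 84.4%, without replicate 3 of the Dox and E2 group. With array weights, whose estimate did not converge, the share was 69.4%. A uniform compression of the deposited values on the Dox arrays in DMSO was argued against. There the SD of the levels of these clusters was at least 0.989 times that on the arrays without Dox, while the responses shrank to 0.515. Normalisation, whose method is not given, can even out this spread, so the test cannot decide on a compression before that step. A level already raised by Dox before E2 was argued against as the whole cause, since 88.3% of the 1223 clusters not higher with Dox in DMSO also had a smaller rise. An effect of doxycycline itself stays open beside an effect of lower CTR9, with 0 arrays of cells given doxycycline without the hairpin, and the lower ESR1 level with Dox was not tested as a cause.

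The counts were set against other arrangements of the arrays. The real splits gave 3575, 739, 6085 and 5492 clusters for E2 without Dox, E2 with Dox, Dox in DMSO and Dox in E2, and the highest of the other 9 splits of each 6 arrays gave 0, 0, 1 and 0, where 10 splits are too few for a share under 0.05 (1 of 10 reached the real count each time, the real one itself). For the average E2 effect 1 of 100 regroupings, the real one, reached 4905 clusters, and the highest other, 3959, kept 10 of the 12 labels. For the average Dox effect 1 of 100, the real one, reached 10678, and the highest other gave 18. Chance was thus argued against for both averages, within the limit of 100 regroupings. For the interaction 2 of 100 arrangements of residuals, the real one included, reached 113 clusters, with 665 as the highest other. For the share of clusters with a smaller response (81.9%) 3 of 100 did, again with the real one included, with 83.7% as the highest other. These shares lie under 0.05, but an arrangement that called several times the real count can point to a structure of the samples, and the cause of that arrangement was not tested.

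Outside the tested clusters, 41 of 1344 other control features and 100 of 1437 probe-region control features were higher with E2 without Dox and 1 and 0 were lower, while the log2 changes of the 23 background features lay between −0.06 and 0.03. With Dox more of them were lower, with 28 of the other control features higher and 42 lower and 26 and 75 of the probe-region features in DMSO, and 13 and 43 and 10 and 113 in E2. In limma 0 of 8 bacterial and phage spike-in features passed with Dox in DMSO, where their median was 0.27 and the lowest 0.05, against a median of −0.00 for 155 ERCC spike-in features, so the overall level stays open. What these control features target is not given in the sources used here.

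Another pattern weighed was the direction of clusters without a gene symbol for Dox in DMSO, where 1865 rose and 804 fell (69.9% higher), against 1093 and 1767 among protein-coding clusters. In E2 the pattern was weaker and turned with the scaling, with 1097 higher and 941 lower, 848 and 1112 after cyclic loess and 635 and 1317 after median centring, so what follows concerns DMSO alone. A trend of differences with signal level was argued against, since the share was 64.9% after cyclic loess (1733 and 939). A single array was argued against for DMSO, since the lowest share without 1 of the 6 arrays was 64.4% (997 and 552, without replicate 1 of the DMSO group without Dox). A difference in overall level between arrays stays open, since median centring gave 57.1% (1312 and 985), between the bounds set for either answer, and no biological explanation was tested.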

How the results depend on the processing

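Cyclic loess, repeated clusters counted once and the lists without replicate 2 of the Dox and DMSO group were chosen after seeing the data. CTR9 was lower and past the threshold in both hormone treatments under every alternative run for it, between −1.62 and −1.48 in DMSO and between −1.79 and −1.74 in E2 with 1 array left out. The 7 counts of clusters stayed within 1.5 times their value under the low-signal filter, quantile normalisation, cyclic loess and repeated clusters counted once. Without the intensity trend the interaction had 63 clusters. Median centring gave 364 for E2 with Dox and 35 for the interaction. Array weights gave 7899 for E2 without Dox, 21500 for E2 with Dox, 22998 for Dox in DMSO, 14060 for Dox in E2, 3302 for the interaction, 17525 for average E2 and 25428 for average Dox, where the estimate did not converge and replicate 1 of the Dox and DMSO group had a weight of 119 and its replicate 2 of 0.108. With these weights the split turned to 39.2% higher for E2 with Dox, 35.5% for average E2 and 56.0% for Dox in E2. The interaction then had 1499 clusters above 0 and 1803 below 0, against 6 and 107 without weights. A fit of only the groups compared gave 87 for E2 with Dox and 3630 for Dox in DMSO, and uses 6 arrays. Clusters of 1 gene gave 6466 for average Dox, from fewer clusters tested. The unmoderated test with a 2-fold change gave 161, 29, 202 and 180 for E2 without Dox, E2 with Dox, Dox in DMSO and Dox in E2, which counts only larger changes. With 1 array left out the counts ran from 2232 to 4769 for E2 without Dox, 249 to 2176 for E2 with Dox, 3746 to 7484 for Dox in DMSO, 3396 to 7642 for Dox in E2, 36 to 147 for the interaction, 3528 to 6693 for average E2 and 8160 to 14035 for average Dox. The share of E2-responsive clusters with a smaller response ran from 57.7% to 88.5% with 1 array left out. Among repressed clusters it ran from 38.1% to 80.3% with 1 array left out, turned to 38.1% without replicate 3 of the Dox and E2 group, and turned to 47.1% with array weights. Except where stated, the cause was not tested.

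A replicate block gave 5535 clusters for E2 without Dox, 2185 for E2 with Dox, 9795 for Dox in DMSO, 8923 for Dox in E2, 358 for the interaction and 7875 for average E2. It also turned the split of the calls for E2 with Dox, from 66.4% to 47.3% higher (1033 and 1152), and for average E2, from 52.5% to 45.3% (3567 and 4308). Residuals of arrays with the same replicate number correlated with r from −0.00906 to 0.420 (median 0.203, 17 of 18 pairs above 0.1), against a median of −0.119 for the 36 other pairs, so the numbers did not meet the requirement that all pairs lie above 0.1. As a hint from the data alone, 11 of 12 arrays correlated best, on average, with the arrays of their own number. The pair not above 0.1 joined replicate 3 of the DMSO group without Dox and replicate 3 of the Dox and DMSO group. The main fit leaves any pairing by replicate number out, so its counts and splits are to be read beside those of the block.

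Of 135 results for named genes 106 passed, 20 of these did not pass under at least 1 alternative run for them, 11 passed only under an alternative and 0 turned direction, where named genes of low signal have no value under the filter on low signal. Median centring ended 15 calls, a fit of only the groups compared 8, quantile normalisation 4, cyclic loess 4 and no intensity trend 3. Of 105 list results 31 lost their call with an estimated correlation, and 8 did with cyclic loess, 8 with quantile normalisation, 6 with median centring and 13 without replicate 2 of the Dox and DMSO group. Lists gained a call in 2, 3, 2 and 2 results under these last 4 alternatives. With a replicate block 1 list result lost its call and 5 gained one. Signal over background limits clusters of low level, and the 7 counts stayed within 1.5 times when the clusters of lower mean signal were left out.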

Other observations

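The lists of BMP targets, keratinocyte differentiation genes and snoRNA hosts, and their tests, were chosen only after the results that prompted them were seen.

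Dox raised 9 genes in DMSO and lowered them in E2, and 0 genes went the other way. TFF1 is the largest example. DTL changed by 0.36 in DMSO and −0.43 in E2, the transcription factor E2F6 by 0.27 and −0.51, the proton pump subunit ATP6V1C2 by 0.31 and −0.44, and FMN1, which nucleates actin filaments, by 0.47 and −0.22. The glucose transporter SLC2A1 (0.35 and −0.21), the nucleolar protein gene NOL6 (0.36 and −0.19), the amino acid transporter SLC7A6 (0.30 and −0.20) and the replication factor MCM10 (0.25 and −0.24) completed the set. Some passed narrowly, with a limma adjusted p in DMSO of 0.0494 for E2F6 and 0.0320 for DTL. In E2 it was 0.0471 for SLC7A6, 0.0407 for FMN1 and 0.0352 for SLC2A1. The set was not drawn again under the alternatives. All 9 rose with E2 without Dox and 6 of them also rose with E2 with Dox, FMN1 by 1.53 and 0.84. All 9 passed the test of the interaction, which is the difference of these same Dox effects.

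Several genes of the cornified envelope and keratinocyte differentiation rose with Dox on average over both hormone treatments. KRT10, a keratin of differentiating epidermis, rose by 1.06, the envelope precursors SPRR1B by 0.84, SPRR3 by 0.84 and SPRR1A by 0.59, the crosslinking enzyme TGM1 by 0.46 and S100A8 by 0.40. In all 12 of 28 genes rose and 0 fell. The hypothesis, prompted by higher GRHL1, CLCA2 and TCHHL1, was that this group rose together, and its median was 0.13 (camera p = 0.0387 with an estimated correlation, and 0.116 adjusted over the 3 lists), so the hypothesis did not pass and stays open.

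Lower BMP7 with Dox prompted the hypothesis that BMP targets fell. MSX2 (−0.51), ID1 (−0.39) and SMAD6 (−0.34) were among 4 of 16 measured targets that fell, and BAMBI (0.31), ID3 (0.30) and ID2 (0.29) were the 3 that rose. For the hypothesis of lower expression of BMP target genes the median was −0.025 (camera p = 0.402 with an estimated correlation, 0.417 adjusted over the 3 lists), and members that moved both ways leave the hypothesis undecided.

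Among 247 clusters of small nucleolar RNAs 29 rose and 3 fell with Dox in DMSO (camera p = 0.492 with an estimated correlation), with 25 and 5 after cyclic loess and 24 and 4 after median centring. In E2 the counts were 13 and 5 (camera p = 0.710 with an estimated correlation), 11 and 8 after cyclic loess and 9 and 11 after median centring, which turns the split. The hypothesis of higher expression of snoRNA host genes could not be decided, since only 5 of 25 hosts were measured as single-gene clusters (median −0.012, p = 0.417 with an estimated correlation).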
